A study of Homo sapiens with 6 samples.

How the data were processed

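Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts and tags open DNA, in 6 libraries of human cells, each made from 50000 cells per the labels. Of these, 2 came from cardiomyocytes sorted out of engineered heart tissues at day 30 of differentiation (20 days after casting), 1 from the fibroblasts sorted out of such tissues, and 3 from column-purified cardiomyocytes at day 10, the kind of cell from which the tissues were cast. The labels call the libraries of a group biological replicates and do not say what differed between them, so errors here measure the spread between these libraries, which may be partly technical. Day, culture format, medium, dissociation enzyme and purification all differ between the tissue and day 10 groups and cannot be separated.

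The deposited files are peak lists, called for each library on its own. Per the submitters' processing notes, FastQC, Bowtie2 2.3.5, Picard, SAMtools, MACS2 and deepTools were used, with the genome build GRCh38; which tool did which step, the calling thresholds, and whether read ends were shifted for the transposase are not given in the sources used here. Every deposited peak is 501 bp wide on chromosomes 1 to 22 or X, and neighbouring peaks of a library overlap. The deposited score of each peak is the authors' own, on a scale that the files do not name, and it was used only to rank peaks within a list. The files hold no read counts, so the sequencing depth is unknown. Lists of the tissue groups were longer than those of day 10. A deeper library gives a longer list, so lists were made equal in length before they were compared.

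Overlapping peaks of a library were merged, and merged peaks were ranked by the highest score in them. A merged peak was called strong if it was among the 50000 highest of its library and listed if it was among the 150000 highest. Regions were the union of the strong peaks of the 6 libraries, with a minimum overlap of 1 bp. A region was called tissue-only if it overlapped a strong peak in both tissue cardiomyocyte libraries and no listed peak in any day 10 library. It was called day-10-only if it overlapped a strong peak in all 3 day 10 libraries and no listed peak in either tissue cardiomyocyte library. The classes thus differ in how many libraries had to hold a region and how many had to lack it. Cardiomyocyte-only and fibroblast-only regions were defined the same way within the tissue, against the single fibroblast library. Lists of equal length do not make absence equal. The lowest score of a listed peak was 14.2 and 13.0 in the tissue cardiomyocyte libraries and 5.61 to 6.10 in the day 10 libraries. More called peaks fell below the cut in the longer tissue lists, so a region not listed there may still hold a called peak. Each region was given to the protein-coding gene whose body was nearest within 100 kb, from a table of 19970 protein-coding genes on GRCh38; between overlapping genes the shorter was taken. The gene table holds gene starts and ends without strand, exons or sequence. The nearest gene body therefore replaced the nearest transcription start site that had been planned, a position within 1 kb of either gene end replaced the promoter, and exons were not told apart from introns. Ranking used the score alone in place of the planned q value and fold enrichment. Motif counts, with their alternatives for GC content and window, were planned and not run, since no genome sequence was used here.

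The Jaccard index (bases shared over bases covered) of strong peaks was compared within and between the groups of cardiomyocyte libraries by an exact one-sided permutation test. Per gene, tissue-only regions were tested against day-10-only regions by an exact two-sided binomial test against their share over all genes, with Benjamini-Hochberg adjustment over genes with at least 5 such regions and a threshold of 0.05. Each of 22 gene lists, fixed before the data were examined (401 of 403 symbols matched, 28 of them in more than 1 list), was tested by its share of tissue-only regions against 10000 random lists matched on regions per gene in 10 bins, two-sided and adjusted over the lists tested. That p runs across genes and not across libraries, and neighbouring regions of a gene are not independent. The binomial p of a gene counts such regions as independent and holds no spread between libraries. For the fibroblast comparison, with 1 library, percentiles among random lists are given without p. Counts of strong peaks per gene and per list in each library were added after the data were examined; 2 libraries against 3 cannot give an exact two-sided p under 0.1. Shares have exact 95% binomial intervals, which cover counting error only. The gene test was also run on simulated data, with changes towards day 10 only, so its power towards the tissue was not measured. It recovered 82% of genes with a 4-fold change in odds and 100% with a 16-fold change at 20 regions per gene, with 0.25% of unchanged genes called. That setting had 1000 genes, whereas 15 were tested in the data, and the called genes held 18 regions (RBFOX1) down to 6 (DPP6). These recovery rates therefore do not carry over to the data. In the simulation with the observed number of regions the test ran on 15 genes and called 0% of the unchanged ones.

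Genes were named by a rule fixed before the data were examined: the called genes of each direction, up to 8, then up to 3 members of each list with the largest difference between the classes, and for the fibroblast comparison the 8 genes with the largest excess of each class and up to 3 members of 6 lists. Members left out of a list as its largest were named after their values were seen, and other genes named outside the rule are said to be. Alternatives were 25000 strong peaks, 100000 listed peaks, every deposited peak as listed, an overlap of 50% of the shorter interval, genes within 50 kb, regions near gene ends left out, and each cardiomyocyte library left out in turn. Assignment to the nearest gene end, 50000 listed peaks, and list ratios without the member with the largest difference in the direction of the list were added after the data were examined; the 50000 were taken from several settings that had been looked at. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and bedtools 2.31.1 was used to check overlaps.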

Results

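Accessible chromatin was profiled in cardiomyocytes before and after their growth in engineered heart tissue, and in the fibroblasts grown with them. The cardiomyocytes were differentiated from AICS-0036-028, an induced pluripotent stem cell line with eGFP at the AAVS1 locus, so that eGFP separated them from the unlabelled cardiac fibroblasts when the tissues were taken apart. There were 2 libraries of tissue cardiomyocytes at day 30, 1 of tissue fibroblasts and 3 of cardiomyocytes at day 10. The tissue cardiomyocyte lists held 779731 and 813313 deposited peaks (217389 and 224982 after merging), the fibroblast list 725774 (208930 merged), and the day 10 lists 482354 to 494167 (169912 to 177771 merged). Sequencing depth was unknown, and lists of equal length were compared. The 50000 strongest peaks of each library gave 88791 regions, of which 21443 were strong in all 6 libraries.

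The first comparison asked how far the open chromatin of cardiomyocytes differed between the tissue and day 10. Replicates shared most of their strong peaks, with a Jaccard index of 0.838 between the 2 tissue cardiomyocyte libraries and 0.812 ± 0.00125 (SD over 3 pairs) among the day 10 libraries. Between the groups the index was 0.525 ± 0.00345 (SD over 6 pairs). The fibroblast library stood further away, at 0.398 from tissue cardiomyocytes and 0.347 from day 10 cardiomyocytes. The mean within groups exceeded that between groups by 0.293, and the real grouping ranked highest of the 10 splits of the 5 cardiomyocyte libraries (exact one-sided permutation test, p = 0.1, the smallest this design can give).

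**Figure D1:**
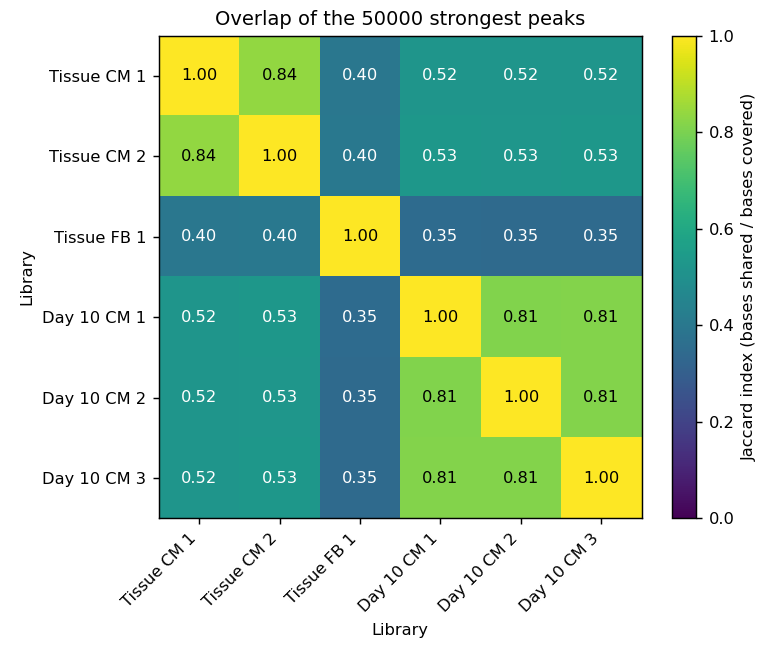
Heat map of the Jaccard index (bases shared over bases covered, colour scale from 0 to 1) of the 50000 strongest peaks, with the 6 libraries on both axes. Mean values are 0.812 among day 10 cardiomyocytes (CM), 0.525 between tissue and day 10 cardiomyocytes, and 0.398 between tissue cardiomyocytes and fibroblasts (FB).

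The cardiomyocyte groups shared 32669 regions that were strong in all 5 libraries. Tissue-only regions numbered 2728 and day-10-only regions 1159. Both classes lay away from gene ends: 1.36% of tissue-only regions (95% interval 0.957 to 1.86) and 5.78% of day-10-only regions (4.51 to 7.28) lay within 1 kb of an end of a protein-coding gene, against 34.1% of the common regions. More of the tissue-only regions lay inside a gene body and over 1 kb from any gene end, 55.4% (53.5 to 57.3), than of the day-10-only regions, 44.0% (41.1 to 46.9). These numbers rested on the cutoffs. Tissue-only against day-10-only regions numbered 2170 against 559 with every deposited peak listed, 5048 against 2455 with 100000 listed peaks, 11880 against 9731 with 50000 listed peaks (a setting added after the data were examined) and 319 against 160 with 25000 strong peaks.

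Most day-10-only regions were spread over the genome, with 899 of them given a gene and 757 genes holding at least 1, while 4 long genes passed a test for an excess of them over tissue-only regions. RBFOX1, which encodes a splicing regulator of neurons and muscle (chromosome 16, 5239721 to 7713340), had 18 day-10-only and 0 tissue-only regions (exact binomial test with Benjamini-Hochberg adjustment, adjusted p = 2.96e-09). It was given 22.7 ± 1.53 strong peaks at day 10 (SD, n = 3), against 1 in each tissue cardiomyocyte library and 1 in fibroblasts. CSMD1, a large membrane protein that regulates complement (chromosome 8, 2935361 to 4994914), had 16 against 0 regions (exact binomial test, adjusted p = 1.77e-08), and 19.3 ± 0.577 strong peaks at day 10 against 0 in the tissue libraries of both cell types. COL22A1, a collagen of tissue junctions (chromosome 8, 138588235 to 138914041), had 8 against 0 (exact binomial test, adjusted p = 0.000243), with 8.67 ± 0.577 strong peaks at day 10, 0 in tissue cardiomyocytes and 9 in fibroblasts. DPP6, an accessory subunit of potassium channels (chromosome 7, 153748133 to 154894285), had 6 against 0 (exact binomial test, adjusted p = 0.00218), with 16 ± 1 strong peaks at day 10, 2 in each tissue cardiomyocyte library and 1 in fibroblasts. The binomial p values count neighbouring regions of a gene as independent and hold no spread between libraries, so they can overstate the evidence. These 4 of the 15 genes with enough regions passed the test towards day 10 (5 at an unadjusted p under 0.05, with TMEM132B, at 1 tissue-only and 4 day-10-only regions, the other), and 0 passed towards the tissue (0 unadjusted). At least 11 tissue-only regions with 0 day-10-only regions were needed for an unadjusted p under 0.05 in that direction, and the highest number at any gene was 7. Tissue-only regions made up 71.1% of the regions of both classes given a gene, the share against which each gene was tested. Small counts of tissue-only against 0 day-10-only regions therefore say little by themselves. With 25000 strong peaks 1 gene passed towards day 10, RBFOX1, and with regions given to the nearest gene end also 1, COL22A1.

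**Figure D2:**
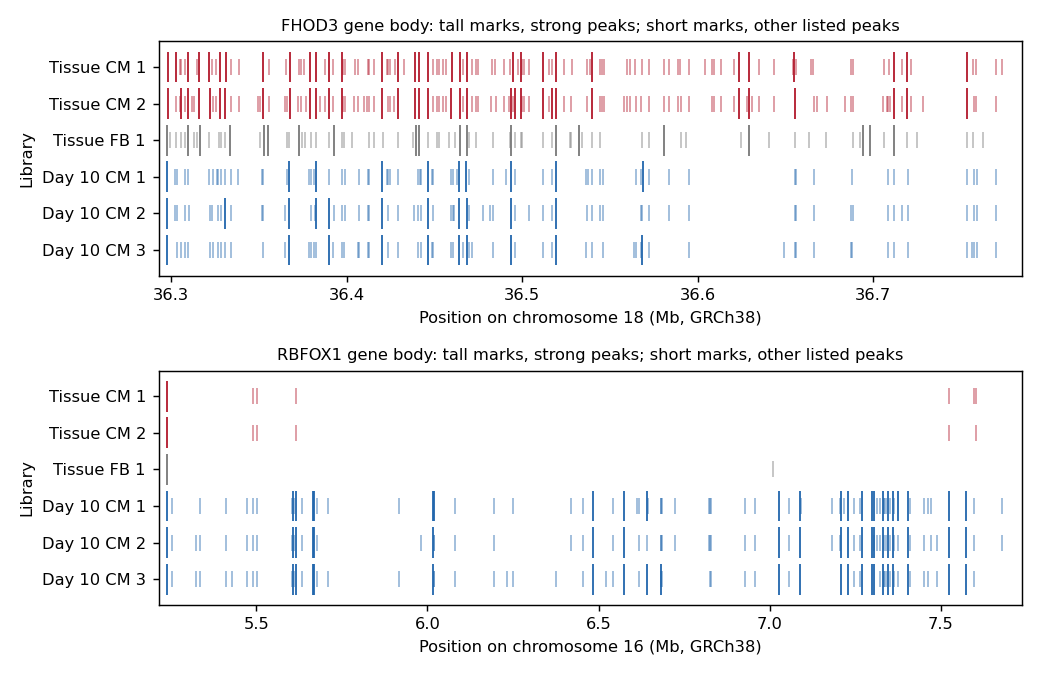
Listed peaks of each of the 6 libraries along FHOD3 (top) and RBFOX1 (bottom), with position in Mb (GRCh38) on the horizontal axis; tall marks are strong peaks and short faint marks the other listed peaks. Inside RBFOX1 the tissue cardiomyocyte libraries list 7 and 6 peaks and the day 10 libraries 69 to 74, and FHOD3 has 32 and 34 strong peaks in tissue cardiomyocytes against 10 or 11 at day 10.

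Calcium handling genes, and to a smaller extent sarcomere genes, held more strong peaks in tissue cardiomyocytes than at day 10, in counts per list that no test supported. The 32 sarcomere genes together held 188 ± 1.41 strong peaks in tissue cardiomyocytes (n = 2) and 143 ± 3.21 at day 10 (n = 3), a ratio of 1.31 (1.27 to 1.34 over pairs of libraries), and 118 in fibroblasts. Of these genes 17 had more strong peaks in the tissue, 10 fewer and 5 as many, and without FHOD3 the ratio was 1.17. FHOD3, a formin that assembles actin filaments of the sarcomere (chromosome 18, 36297713 to 36780220), had 33 ± 1.41 against 10.3 ± 0.577 strong peaks, with 20 in fibroblasts, and 4 tissue-only against 0 day-10-only regions. MYOM1, a protein of the M-band, had 10.5 ± 0.707 against 6 in each day 10 library (2 against 0 regions), whereas its paralogue MYOM2 had 1.5 ± 0.707 against 7 (0 against 2 regions). The 21 calcium handling genes held 174 ± 1.41 against 115 ± 2.52 strong peaks, a ratio of 1.52 (1.48 to 1.56), and 122 in fibroblasts; 16 members had more, 4 fewer and 1 as many, and the ratio was 1.44 without RYR2, the member with the largest difference. TRDN, the triadin of the calcium release complex, had 11 in each tissue cardiomyocyte library, 2 in each day 10 library and 0 in fibroblasts (4 against 0 regions), and JPH1, a junctophilin, 8.5 ± 0.707 against 5 (2 against 0 regions). CACNA2D1, a calcium channel subunit, had 7 against 4 (2 against 0 regions) and 11 in fibroblasts. The 28 cardiomyopathy genes, which share members with these lists, had a ratio of 1.26 (197 ± 2.83 against 157 ± 6.66), and of 1.12 without FHOD3, with CSRP3 at 6 ± 1.41 against 2. The 14 fetal and atrial contractile genes had a ratio of 1.19, which fell to 0.919 with 25000 strong peaks.

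Within the fatty acid oxidation list the difference lay almost wholly at PPARGC1A. The 33 genes of fatty acid oxidation held 140 ± 0.707 strong peaks in tissue cardiomyocytes and 120 ± 1.53 at day 10, a ratio of 1.17, and 82 in fibroblasts; without PPARGC1A the ratio was 1.02. PPARGC1A, the coactivator that drives mitochondrial genes, had 28.5 ± 2.12 against 11 ± 1 strong peaks and 4 in fibroblasts; its 6 tissue-only against 0 day-10-only regions did not pass the exact binomial test (adjusted p = 0.383 after Benjamini-Hochberg adjustment). The glucocorticoid and insulin response list had a ratio of 1.40 (92 ± 1.41 against 65.7 ± 0.577; 100 in fibroblasts), with ZBTB16, a glucocorticoid-induced repressor, at 20 against 13.7 ± 0.577, and of 1.31 without IRS1, the member with the largest difference. The TGF-β and myofibroblast list had a ratio of 1.27 (105 ± 5.66 against 83 ± 2.65, with 134 in fibroblasts), and of 1.15 without SMAD3. This list had 10 tissue-only against 0 day-10-only regions, where matched random lists had a median tissue-only share of 77.8% (permutation test, unadjusted p = 0.406). Of its members, LTBP1, which tethers latent TGF-β to the matrix, had 19 ± 1.41 against 8.33 ± 0.577 strong peaks and 19 in fibroblasts (4 against 0 regions), and TGFBI, a TGF-β-induced matrix protein, 7 against 2.67 ± 0.577 and 17 in fibroblasts (3 against 0 regions). Glycolysis and hypoxia genes had a ratio of 1.08 (1.01 to 1.14) and YAP and TEAD targets of 1.10 (1.08 to 1.13), or 1.05 and 1.04 without their largest members, SLC2A1 and TEAD1. Ion channel genes (ratio 1.01) and cardiac transcription factors (0.982) differed little; over pairs of libraries the ratio ran from 0.970 to 1.05 for the first list and from 0.970 to 0.990 for the second.

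Lists of earlier stages and of some other lineages held fewer strong peaks in tissue cardiomyocytes. The ratio was 0.775 for mesoderm and cardiac progenitor genes (62 ± 4.24 against 80), with ISL1, a transcription factor of cardiac progenitors, at 3 against 7 ± 1. It was 0.576 for pluripotency genes (16.5 ± 0.707 against 28.7 ± 1.53), 0.714 for neural, 0.685 for epicardial, 0.773 for endothelial and 0.837 for endoderm genes. Without the member with the largest difference it was 0.808 for mesoderm and cardiac progenitor genes (ISL1 left out), 0.702 for pluripotency (SOX2), 0.750 for neural (GFAP), 0.800 for epicardial (TCF21) and 0.826 for endothelial genes (CDH5). Endoderm genes, with 3 members higher, 3 lower and 5 equal, stood at 0.967 (0.875 to 1.07) without HNF4A. For blood and immune genes the ratio was 0.794, reaching 1 in a pair of libraries, and smooth muscle and pericyte genes stood at 1.05 (0.982 to 1.11). Members of these lists went both ways. In the tissue 4 mesoderm and cardiac progenitor, 4 endothelial and 2 epicardial genes were higher, and 14, 8 and 7 lower. The higher ones included WNT5A (3 ± 1.41 against 1.67 ± 0.577), ERG (7 ± 1.41 against 5.67 ± 0.577), TEK (3 against 1) and SEMA3D (4 against 1.33 ± 0.577). Endothelial genes had 5 tissue-only against 2 day-10-only regions. Within the cardiac transcription factors, HEY2 (2 against 4.33 ± 0.577) and IRX4 (1 against 3.33 ± 0.577), both factors of ventricular muscle, had fewer strong peaks in the tissue, and MEIS2 had more (19 ± 1.41 against 14 ± 1). Fibroblast and extracellular matrix genes stood at 1.05 (90 ± 2.83 against 86 ± 1.73), above 1 in every pair of libraries, at 0.974 with 25000 strong peaks and at 0.988 without COL6A3, while fibroblasts held 185.

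**Figure D3:**
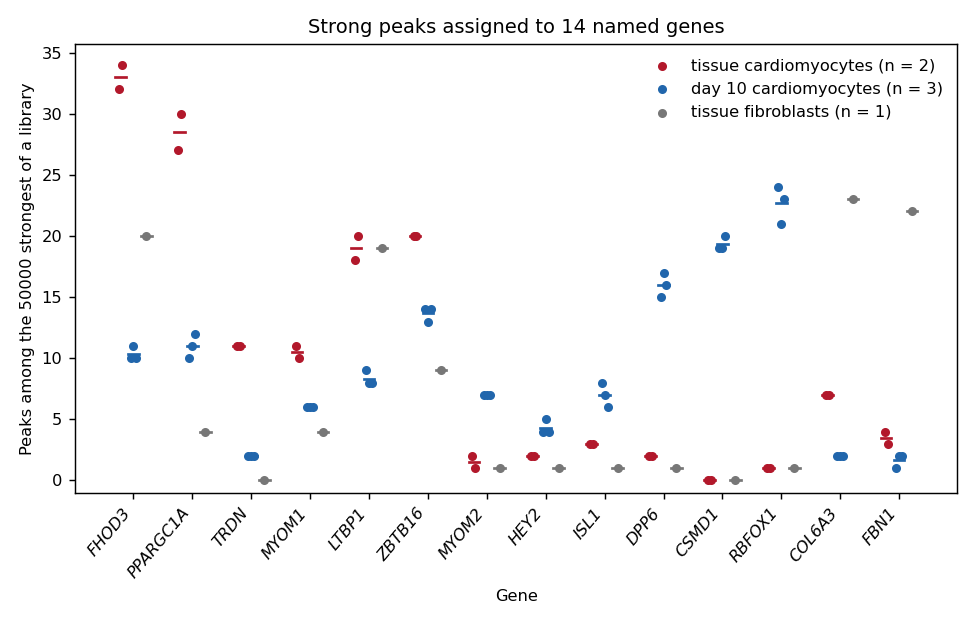
Number of strong peaks given to 14 named genes (vertical axis), with a point per library and a line at the mean of each group; tissue cardiomyocytes have 2 libraries, day 10 cardiomyocytes 3 and fibroblasts 1. FHOD3, PPARGC1A and TRDN lie higher in both tissue cardiomyocyte libraries than in any day 10 library, and RBFOX1, CSMD1 and DPP6 lie lower.

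Of the 22 lists, 11 had a ratio over 1 and 7 a ratio under 1 in every pair of libraries. The direction of some rested on 1 member. Cell cycle genes stood at 1 without CCND3, cardiac transcription factors at 1.00 without HAND1, and fibroblast and extracellular matrix genes at 0.988 without COL6A3. Such counts could not reach an exact two-sided permutation p under 0.1 and were chosen after the data were examined. The ratios were not set against those of matched random lists, so a ratio away from 1 need not be particular to a list. The planned test, on tissue-only against day-10-only regions, could be made for 9 lists, and 0 passed (0 at an unadjusted p under 0.05; smallest adjusted p = 0.856 in a permutation test). Its regions were few: sarcomere genes had 12 tissue-only and 2 day-10-only regions, with 7 members leaning to the tissue, 1 to day 10 and 24 to neither, and calcium handling genes 16 and 2, with 10, 2 and 9 members. The tissue-only shares of these lists were 85.7% and 88.9%, beside medians of 75% and 77.8% in matched random lists. With medians this high the test had little room towards the tissue. The TGF-β and myofibroblast list, at a share of 100%, had an unadjusted p of 0.406 (permutation test). That 0 lists passed therefore says little about a lean to the tissue. PPARGC1A was the only list member with enough regions for the gene test, so 0 list members were called, over all genes or adjusted over the list alone.

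The next comparison set cardiomyocytes against fibroblasts of the same kind of tissue, with 1 fibroblast library and hence no replicate check. Cardiomyocyte-only regions numbered 1705 and fibroblast-only regions 11240. Among genes with the largest excess of cardiomyocyte-only regions were PPARGC1A (5 cardiomyocyte-only against 0 fibroblast-only; 28.5 ± 2.12 strong peaks in cardiomyocytes against 4), PTPRD, a receptor phosphatase (5 against 0; 29 ± 1.41 strong peaks against 3), ENOX1 (6 against 2), the chromatin remodeller CHD7 (4 against 0) and NOS1AP, a gene tied to the QT interval (4 against 0). Fibroblast-only regions led at genes of several kinds: FRMD4A (14 against 1 cardiomyocyte-only), the nuclear receptor RORA (13 against 0), SASH1 (13 against 0) and the matrix genes FBN1, fibrillin (14 against 0 cardiomyocyte-only; 22 strong peaks in fibroblasts against 3.5 ± 0.707), and COL6A3, a collagen VI chain (13 against 0; 23 against 7). DCN, decorin, had 6 fibroblast-only and 0 cardiomyocyte-only regions, and PECAM1, an endothelial adhesion molecule, 4 and 0, with 7 strong peaks in fibroblasts and 0 in either cardiomyocyte group.

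The share of cardiomyocyte-only regions was described for 19 lists. The fibroblast and extracellular matrix list had 0 cardiomyocyte-only and 70 fibroblast-only regions, a share at percentile 0.635 of matched random lists. Endothelial genes had 0 and 27 (percentile 5.67) and TGF-β and myofibroblast genes 1 and 25 (percentile 8.34). Fatty acid oxidation genes had 9 and 7 (percentile 100), of which PPARGC1A alone held 5 and 0, cardiomyopathy genes 6 and 7 (percentile 99.9), sarcomere genes 10 and 15 (percentile 99.8) and cardiac transcription factors 10 and 25 (percentile 97.3). Calcium handling genes had 7 and 24 (percentile 86.9). Percentiles were 93.5 for mesoderm and cardiac progenitor, 92.4 for smooth muscle and pericyte, 90.0 for ion channel and 83.7 for epicardial genes. They were 54.2 for cell cycle, 50.1 for glucocorticoid and insulin response, 41.5 for YAP and TEAD, 37.4 for glycolysis and hypoxia, 35.1 for endoderm, 33.7 for AP-1 and immediate early stress and 27.3 for blood and immune genes. The numbers of both classes and the gap between them rested on the cutoffs. Cardiomyocyte-only against fibroblast-only regions numbered 38 against 7105 with every deposited peak listed, 8788 against 15769 with 100000 listed peaks, 20904 against 22641 with 50000 listed peaks and 0 against 3015 with 25000 strong peaks.

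The last comparison asked how many regions gained against day 10 were also open in the fibroblasts of the tissue. Of the tissue-only regions, 2356 of 2728, or 86.4% (95% interval 85.0 to 87.6), overlapped a listed fibroblast peak, and 29.8% overlapped a strong one. Of the day-10-only regions 13.4% (11.5 to 15.5) overlapped a listed fibroblast peak, and of the regions strong in all 5 cardiomyocyte libraries 98.8%. Of all regions strong in both tissue cardiomyocyte libraries 96.4% did so, and of all regions strong in the 3 day 10 libraries 87.8%. The share rested on the cutoffs. For tissue-only regions it was 56.5% with 100000 listed peaks, and 10.0% of day-10-only regions were then shared. With 50000 listed peaks these shares were 31.3% and 6.95%, with every deposited peak listed 99.4% and 18.6%, and with 25000 strong peaks 100% and 21.3%.

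**Figure D4:**
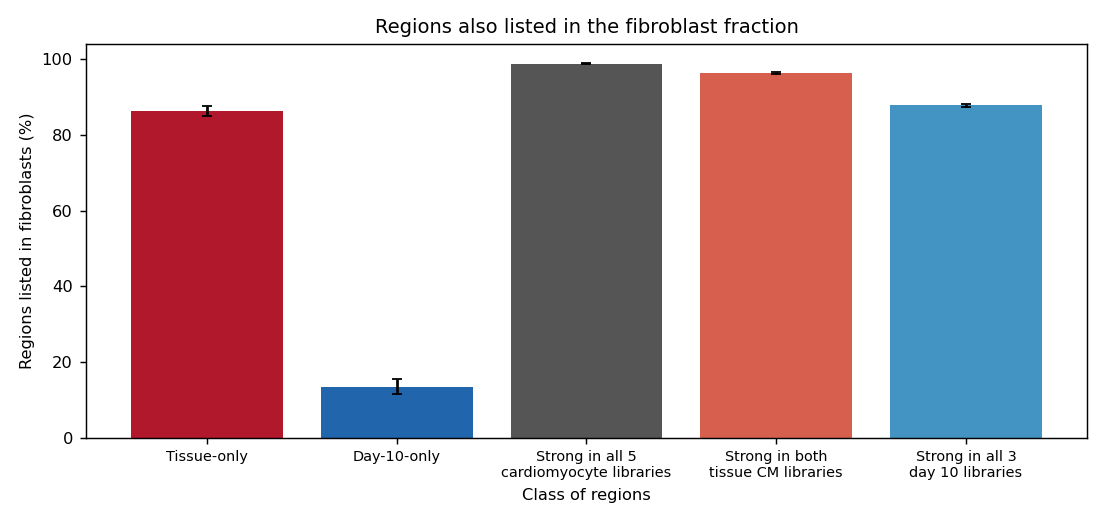
Percent of the regions of each class that overlap a listed peak of the fibroblast library, with exact 95% binomial intervals. Tissue-only regions stand at 86.4% and day-10-only regions at 13.4%.

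**Figure D5:**
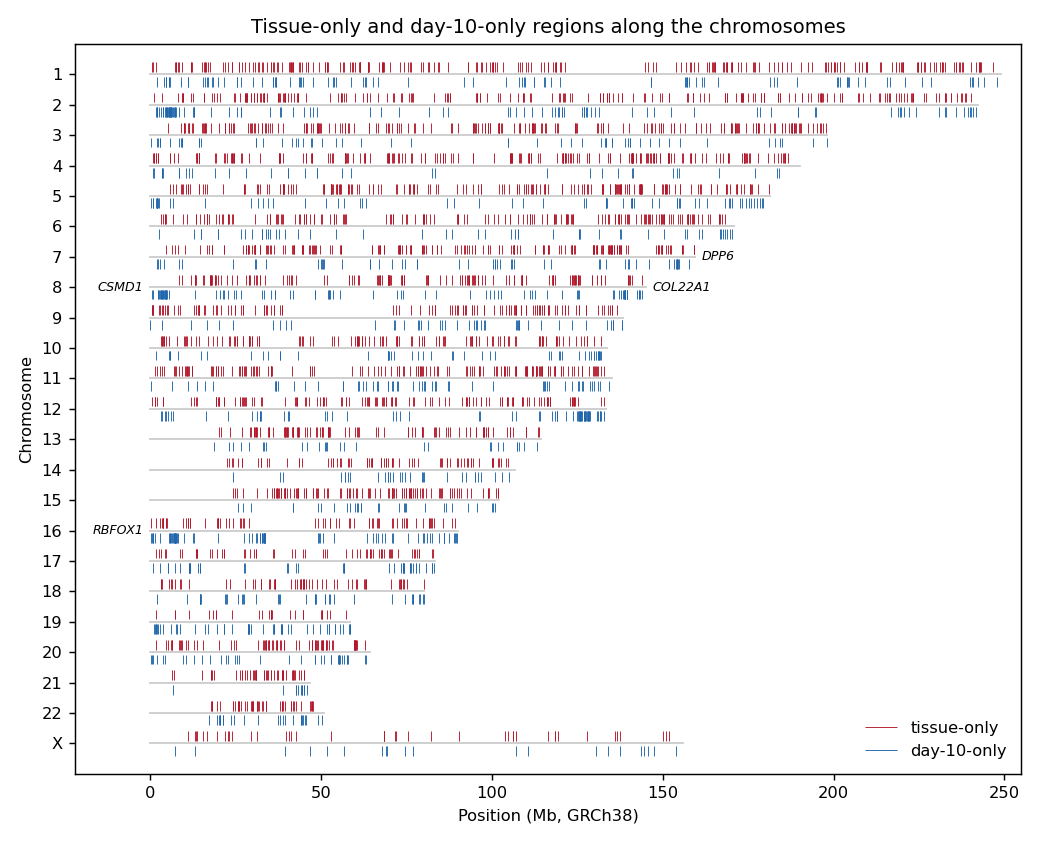
Positions of tissue-only and day-10-only regions along the chromosomes, in Mb (GRCh38), with each region a mark above (tissue-only) or below (day-10-only) its chromosome; the 4 genes called towards day 10 are named at the chromosome end nearest to them. The map shows 2728 tissue-only and 1159 day-10-only regions.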

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

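Assignment to the nearest gene end, 50000 listed peaks and leaving out the largest member of a gene list were chosen after the data were examined, the 50000 from several settings already looked at. Numbers of regions follow in the order tissue-only, day-10-only, cardiomyocyte-only and fibroblast-only. With 25000 strong peaks they were 319, 160, 0 and 3015, with 1 gene called towards day 10, a fibroblast share of 100% and a Jaccard difference of 0.274. With every deposited peak listed, day-10-only regions numbered 559, cardiomyocyte-only 38 and fibroblast-only 7105, and the share was 99.4%. With 100000 listed peaks, tissue-only regions numbered 5048, day-10-only 2455 and cardiomyocyte-only 8788, and the share was 56.5%. With 50000 listed peaks the numbers were 11880, 9731, 20904 and 22641 and the share 31.3%; 1 gene was called towards the tissue (FHOD3, 20 against 0 regions, adjusted p = 0.00242 in the exact binomial test) and 2 towards day 10 (RBFOX1 and CSMD1), while 0 lists passed (8 of 22 at an unadjusted p under 0.05, smallest adjusted p = 0.103). None of the planned settings called FHOD3, any other gene towards the tissue, or a list, so the FHOD3 call rests on a setting picked with the data in view. With the nearest gene end, 1 gene was called towards day 10. These numbers follow from how many peaks count as strong or listed, or where regions are assigned. Leaving out 1 cardiomyocyte library at a time gave 2957 to 3176 tissue-only, 1266 to 1302 day-10-only, 2274 to 2350 cardiomyocyte-only and 12000 to 12060 fibroblast-only regions, 4 to 5 genes towards day 10, 0 towards the tissue, a share of 83.2% to 86.7% and a Jaccard difference of 0.284 to 0.301. The overlap of 50% of the shorter interval, genes within 50 kb and regions near gene ends left out changed none of the calls. Motif counts and their alternatives were not run. No paired analysis was possible because the results are overlaps of peak sets with no model over samples, and nothing ties the replicate numbers of different groups together. Unknown depth limits every statement that a region was absent from a list.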

Other observations

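The tests on regions not strong in fibroblasts, on a gained segment, on chromosome ends and on each locus by gene were chosen after their results or closely related ones were seen, and so were the reverse correlation, the stretches without peaks, the window tallies and the counts of strong peaks. The remaining gene lists had ratios of tissue cardiomyocytes to day 10 near 1 in strong peaks. The ratio was 1.06 for cell cycle genes, with 7 members higher, 8 lower and 13 equal. It was 0.976 for AP-1 and immediate early stress genes, and turned to 1.025 with 25000 strong peaks, 1.07 with genes within 50 kb and 1.03 without MYC. Genes picked after their values were seen included ITGA1, a collagen-binding integrin, and PHACTR3, a regulator of actin and phosphatase 1, each with 7 tissue-only and 0 day-10-only regions; ITGA1 had 10 strong peaks in tissue cardiomyocytes on average and 2 at day 10. RYR2, the calcium release channel of the heart, had 22.5 strong peaks on average in tissue cardiomyocytes, 9.33 at day 10 and 1 in fibroblasts.

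Most tissue-only regions were also listed in the sorted fibroblasts, and fibroblasts left in the cardiomyocyte fraction may account for part of them. The test fixed beforehand left this undecided: 86.4% were listed in fibroblasts, between the bounds of 90% for carry-over and 50% against it. At other cutoffs the share passed either bound, at 31.3% with 50000 listed peaks and 100% with 25000 strong peaks. Of all regions strong in both tissue cardiomyocyte libraries 96.4% were listed in fibroblasts, so a share over 90% would not single out carry-over. A further test, taken up only because the planned one was undecided and with its value already known, argued against carry-over as the source of most of the set, since 70.2% of the regions were not strong in fibroblasts. As that test was picked with its value in view, it does not exclude carry-over. The 372 tissue-only regions not listed in fibroblasts are least open to it, but 1 fibroblast library measured this. Carry-over stays most open for the 813 regions also strong in fibroblasts, and 99.4% of tissue-only regions had some fibroblast peak. The planned test of the shared part was undecided too. Of the strongest 10% of fibroblast regions outside every day 10 list, 57.4% (55.0 to 59.8) were listed in both tissue cardiomyocyte libraries. In this strongest part 9.87% were strong in both libraries and 34.3% listed in neither. Of the weakest 10%, 21.1% were listed in both. Shorter day 10 lists stay open too, as 79.5% (78.0 to 81.0) of the tissue-only regions had no peak in the full day 10 lists. Of the day-10-only regions, 48.2% (45.3 to 51.2) had no peak in the full, longer tissue cardiomyocyte lists. The 10 splits of the 5 libraries (1 as large, 2728 regions, highest other 0) are too few to judge chance, and age and culture were not separable.

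Fibroblasts listed nearly all regions strong in tissue cardiomyocytes, and cardiomyocytes left in the eGFP-negative fraction are a candidate explanation. Over the 20904 regions strong in both tissue cardiomyocyte libraries and not in fibroblasts, the fibroblast score followed the tissue cardiomyocyte score with Spearman rho 0.441, more closely than the day 10 score (0.379), as carry-over predicts; regions are not independent replicates. The reverse relation, of cardiomyocyte to fibroblast score over regions strong in fibroblasts and not in both tissue cardiomyocyte libraries, was weaker (0.199). Low-level openness of these regions in fibroblasts was not tested, and such carry-over would also raise the 86.4% above.

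Windows of 1 Mb with at least 3 regions held 339 of 1159 day-10-only regions (85 windows) and 1127 of 2728 tissue-only regions (310 windows), with at most 13 and 8 in a window, and no chance expectation was computed; loss of a locus in the cells grown into tissue may account for the day-10-only clusters at RBFOX1 and CSMD1. The fewest listed peaks inside either gene in a tissue cardiomyocyte library was 2, between the bounds of 0 and 5 fixed beforehand, which leaves CSMD1 open, whereas at least 6 inside RBFOX1 argue against loss of that whole gene; loss of a part, or of a stretch reaching past CSMD1, stays open, as neither library had a peak over 1.77 Mb of RBFOX1 (chromosome 16, 5755189 to 7524088) or 1.90 Mb of CSMD1 (chromosome 8, 2935361 to 4837696, from the gene boundary on), though fibroblasts, which are separate cells, had only 1 and 0 peaks there. The day-10-only windows lay on 21 chromosomes, which argues against 1 gained segment in the day 10 cells as the source of all of them. For single clusters a gained segment stays open. Windows of tissue-only regions lay on 23 chromosomes, so spread alone cannot decide for any 1 cluster. Windows with day-10-only regions lay within 10 Mb of a chromosome end more often than those with tissue-only regions (25.4% against 13.3%, two-sided Fisher exact test, p = 2.32e-12, over windows and not libraries). Some windows held both classes, and neighbouring windows of a locus counted as independent, so this p can overstate the evidence. GC content and misassigned reads were not tested, and the difference in age and culture between the groups stays open as a biological explanation.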
